A study of Mus musculus with 2 samples.

How the data were processed

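Cells from enzymatically digested thymus of 2 mouse genotypes were profiled by droplet single-cell RNA sequencing after magnetic depletion of CD45-positive (blood) cells. Per the labels, 1 library came from Ccl25-flox;Wt thymus (control) and 1 from Ccl25-flox;Foxn1-Cre-Tg thymus (conditional knockout, cKO), in which Cre recombinase is driven by Foxn1, the regulator that marks thymic epithelial cells. Both libraries were used, each as a group of 1, and no label column was left unused. Per the submitters' processing notes, the libraries were made with 10x Genomics 3′ v3.1 chemistry and handled with Cell Ranger 7.1.0, STAR 2.7.2a and bcl2fastq 2.20.0 on build mm10. The roles and settings of these tools, the annotation release and the strand rule of the counting are not given in the sources used here. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode from the authors' filtered output, with no normalization, for 32285 genes in each library.

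The deposited control matrix held 5769 barcodes and 78528970 UMIs, and the cKO matrix held 5026 barcodes and 76479791 UMIs. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. These limits left 5153 control and 4506 cKO cells. Scrublet, as part of scanpy, was run on each library with an expected rate of 5% and called 48 control cells (0.931%) and 13 cKO cells (0.289%) as doublets, which were removed. These rates are low, so the removal of the highest 5% of scores in each library was added as an alternative after seeing the data. The final set held 5105 control and 4493 cKO cells.

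Counts were scaled to 10000 per cell and log-transformed. The 3000 most variable genes, without Ccl25, sex-linked genes, ribosomal and mitochondrial genes, gave 30 principal components, a shared-neighbour graph of 15 neighbours and Leiden clusters at resolution 1. The 29 clusters were named from those of 29 marker lists that describe broad cell types. The arterial, venous and lymphatic endothelial lists and the erythroid list gave no names. A name needed at least 3 markers with at least 20 CPM (UMIs of a gene scaled to the total) and at least 2-fold the median cluster, and a mean marker level of at least 0.2 of that in each marker's highest cluster. Among the 10 leading genes it needed no more markers of another class than of its own, and clusters with low UMIs and no own marker there stayed unnamed. Where several names passed, the one with the most markers among the leading genes was taken, then the one with the highest level. Cells with at least 5% haemoglobin UMIs were set aside as erythroid-like before clustering. The 5 clusters of thymic epithelial cells (TEC) were clustered again into 14 subclusters, named from the lists of TEC subtypes with a level of at least 0.4. In all, 23 clusters received 9 names and 6 stayed unnamed. Of the subclusters, 8 received 7 names and 6 stayed unnamed. The thresholds for names and the method that builds the graph were settled after the data were seen, so every class carries the ending -like. Unnamed clusters with at least 200 Ptprc CPM were counted as CD45-type.

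Expression was compared on sums of raw counts per library and class, as CPM of the class. For Ccl25, Foxn1 and its neighbours the ratio of cKO over control was taken directly, with a floor of 3 counts where a library had 0. For profiles a pseudocount of 1 CPM was added and values were put on the log2 scale. Profiles were made for classes with at least 30 cells in each library. The cTEC-like class, with 28 control cells, was profiled all the same because the design names it, and is marked as under that limit. Intervals at 95% are exact Poisson intervals for sums, exact binomial intervals for ratios of sums, exact Clopper-Pearson intervals for shares of cells and Katz intervals for ratios of shares. They cover counting error only. With 1 library per group there are no replicates, so no test between genotypes, no p-value and no count of changed genes is given. The share of cells with a Ccl25 UMI was also computed after each cell was thinned to 2000 UMIs.

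Before the data were examined, 21 gene lists, the marker lists, the rule for named genes and most alternatives were fixed. The lists are chemokines, thymocyte support, cTEC antigen processing, immunoproteasome and class I, class II, TEC transcription factors, medullary maturation, tissue antigens, interferon response, dissociation stress, cell cycle, extracellular matrix, hypoxia and glycolysis, fibroblast growth and morphogen signals, endothelial thymic portal and adhesion, thymocyte receptors, DN stage, DP stage, SP stage, gamma-delta, and CD45-positive carry-over. DN, DP and SP are the double-negative, double-positive and single-positive steps of T cell development. Members with at least 10 CPM in 1 library of a class were used. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on expression in 20 bins, and its counting interval came from 1000 Poisson redraws. Its percentile describes these 2 libraries and is no test across animals. Examples are the list members besides Ccl25, which has its own paragraphs, with the highest absolute log2 ratio among those with at least 50 CPM in 1 library. Named genes are Ccl25, Foxn1, the sex-linked genes and, by size, the 8 highest and 8 lowest log2 ratios in TEC-like and in cTEC-like cells and the 4 highest and 4 lowest in each other class. They needed at least 100 CPM in the higher library, at least 50 UMIs over both, and a level in that library of at least 0.25 of that in its highest class. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and sex-linked genes were excluded from the choice by size. For TEC-like and cTEC-like cells, 1 gene chosen by size in each is not reported here. Neighbours of Foxn1 were singled out after their values were seen.

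Genes chosen by size in the 6 classes with under 100 cells in a library (NK or ILC, mural, mesothelial, myeloid, keratinocyte TEC and tuft TEC) are not listed, a limit chosen after seeing the data. The cTEC-like class is smaller still and is listed as an exception, since the design names it. Of the 47 genes besides Ccl25 in the 6 classes not listed, 21 had more than 50% of their UMIs in 1 cell in the higher library, against 14 of 69 in the 7 classes that are listed. Spt1 and Mx1, members of the tissue antigen and interferon lists, are not among the gene names of the matrices and were left out. Positions come from GENCODE vM21 on GRCm38, of which mm10 is another name.

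The calculation on sums was checked on simulated data, with 200 genes per class given a known log2 change of -2, -1, 1 or 2 in 50 genes each. Class totals were Poisson draws from the pooled profile of both libraries, the model that the intervals assume. The draws held no variation between cells or animals, and lists without a change were random genes. They check the calculation and cannot show how often intervals or lists mislead in the real data. In TEC-like cells (10759 genes) the median recovered values were -1.91, -0.98, 0.97 and 1.94, and the intervals held the true value for 95.5% of the genes. In cTEC-like cells (9242 genes) they were -1.94, -0.99, 0.88 and 2.00, with 96.2% held. In fibroblast-like cells (9265 genes) they were -1.92, -1.00, 0.95 and 1.96, with 95.5% held. Endothelial-like cells (9012 genes) gave -1.91, -1.04, 0.92 and 1.91, with 96.1% held. Thymocyte-like cells (8840 genes) gave -1.92, -0.98, 0.98 and 1.95, with 95.8% held. The direction was right for at least 98% of the changed genes at each size and class. A raised list stood at percentile 100 in each class. Of 40 lists without a change per class, 1 in fibroblast-like and 1 in thymocyte-like cells fell outside the middle 95% of random lists, and 0 did in the other 3 classes.

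The alternatives were a looser filter (200 genes and 500 UMIs), a stricter filter (1000 genes and 2000 UMIs), at most 5% mitochondrial UMIs, doublets kept, resolution 2, each library clustered alone, and subtraction of a free-RNA profile. Others were thinning to 2000 UMIs, median-ratio scaling over genes with at least 50 CPM, a pseudocount of 10 CPM, equal weight per cell, no filter on low genes, and shares without blood classes. The free-RNA profile was the sum of thymocyte-like and erythroid-like cells of the same library. It was scaled to each class by Cd3e, Cd8b1, Cd4, Rag1 and haemoglobin UMIs, and counts under 0 were set to 0. Added after seeing the data were the removal of the highest 5% of doublet scores, the omission of TEC subclusters led by genes of another class, and the omission of each library's cell with the most UMIs of a named gene. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.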

Results

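The data were single-cell transcriptomes of thymus cells from 1 control library (Ccl25-flox;Wt) and 1 cKO library (Ccl25-flox;Foxn1-Cre-Tg), so there were no replicates. The intervals cover counting error only, and differences between animals or in handling cannot be told apart from genotype. The stated purpose was to find which thymic cells express Ccl25, a chemokine made in thymus and gut, and how its loss affects the cell populations of the thymus. The control library held 78528970 UMIs in 5769 barcodes, with a median of 9592 per barcode, and the cKO library held 76479791 UMIs in 5026 barcodes, with a median of 11687.5. After filtering, 5105 control cells (median 11110 UMIs and 3701 genes) and 4493 cKO cells (median 12982 UMIs and 3991 genes) remained. Both libraries had the sex-linked pattern of male tissue, with 6529 and 7558 UMIs of the Y-linked gene Ddx3y and 21 and 19 UMIs of Xist in control and cKO. Haemoglobin RNA was higher in control, where Hbb-bs stood at 346 CPM against 58.7 CPM in cKO.

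Which cells express Ccl25 was read from the control library. Ccl25 (ENSMUSG00000023235, chromosome 8, 4325210 to 4360020 on GRCm38) was mainly an epithelial transcript there, and 82.4% of its UMIs lay in TEC-like cells. Cortical (cTEC-like) cells, which rear early thymocytes, were highest at 7658 CPM [7453, 7867], 13.1-fold over the rest of the TEC-like cells, although only 28 cells carried that name. Aire mTEC-like cells, the medullary cells that display tissue antigens, had 569 CPM. Microfold TEC-like and keratinocyte TEC-like cells had 370.3 and 287 CPM, and the proliferating, tuft and neuroendocrine types had 38.9, 35.5 and 33.5 CPM. The keratinocyte subcluster also had ciliated-type markers at a level of 1, above the 0.884 of its keratinocyte markers. The microfold subcluster had enterohepatic markers at 0.774, with Fabp1 among its leading genes, so these names may cover mixed types. Of the unnamed TEC subclusters, the mixed subcluster led by thymocyte genes had 3102 UMIs (1979 CPM), subcluster 4, whose cells had few UMIs, had 636 UMIs (2403 CPM), and subclusters 1, 5, 12 and 13 had 87, 18, 7 and 1 UMIs. Subcluster 5 had 7 raised markers of Ccl21-type medullary cells, but mural genes outnumbered them among its leading genes. Cells outside the TEC-like class had 43.2 CPM [41.6, 44.9], with 55.1 CPM in thymocyte-like, 25.5 CPM in fibroblast-like and 26.2 CPM in endothelial-like cells. In control, 92.9% of cTEC-like cells (median 17165.5 UMIs) and 53.0% of TEC-like cells (median 17374 UMIs) had a Ccl25 UMI, against 37.5% of thymocyte-like cells (median 6608 UMIs) and 17.1% of endothelial-like cells (median 6029 UMIs). With each cell thinned to 2000 UMIs these shares were 73.1%, 19.5%, 10.96% and 4.51%. No free RNA was subtracted from these control values, so those outside the TEC-like class include it.

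The cKO library tested the effect of the deletion on Ccl25 itself. In TEC-like cells Ccl25 went from 953 CPM [937, 970] to 3.11 CPM [2.15, 4.35], from 12670 to 34 UMIs, a log2 ratio of -8.26 [-8.79, -7.78]. In cTEC-like cells it went from 5300 UMIs to 0 UMIs, at least 2750-fold lower against a floor of 3 counts in the cKO class. Aire mTEC-like cells went from 2807 to 2 UMIs, a log2 ratio of -10.07 [-13.12, -8.22], and microfold TEC-like cells from 264 to 0 UMIs, at least 40.7-fold lower against the same floor. The counts went from 365 to 2 UMIs in keratinocyte, 53 to 1 in proliferating, 24 to 3 in tuft and 6 to 0 in neuroendocrine TEC-like cells. Of the 34 UMIs left in cKO TEC-like cells, 44.1% lay in a mixed subcluster led by thymocyte genes. The share of cells with a UMI in cKO was 4.55% of TEC-like cells (median 15567 UMIs) and 0 of 41 cTEC-like cells, against 40.7% of thymocyte-like (median 11980 UMIs) and 11.9% of endothelial-like cells (median 5276 UMIs).

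Outside the TEC-like class Ccl25 was still present but lower, at 34.8 CPM [33.3, 36.2] or 2219 UMIs in cKO, a log2 ratio of -0.32 [-0.40, -0.23] that moved to -0.71 with the looser filter. With that filter the TEC-like class held 537 control and 500 cKO cells, against 613 and 550 in the chosen analysis. Cells counted outside it may then include epithelial cells, so -0.71 does not measure a larger fall in other cell types. Thymocyte-like cells had 44.6 CPM, B cell-like cells 28.6 CPM, endothelial-like cells 19.5 CPM and fibroblast-like cells 18.6 CPM in cKO. TEC-like cells thus went from holding 82.4% of the Ccl25 UMIs of the library to holding 1.51%. The deleted exons are not given in the sources used here. Whether the 3′ tags lie in the deleted part is therefore unknown, although the UMIs counted in TEC-like cells fell in cKO. The annotated 3′ untranslated region of Ccl25-201 lies in exon 6 of 6, from 4359513 to 4360020, and the 5′ end of the gene overlaps Elavl1 on the other strand.

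**Figure D1:**
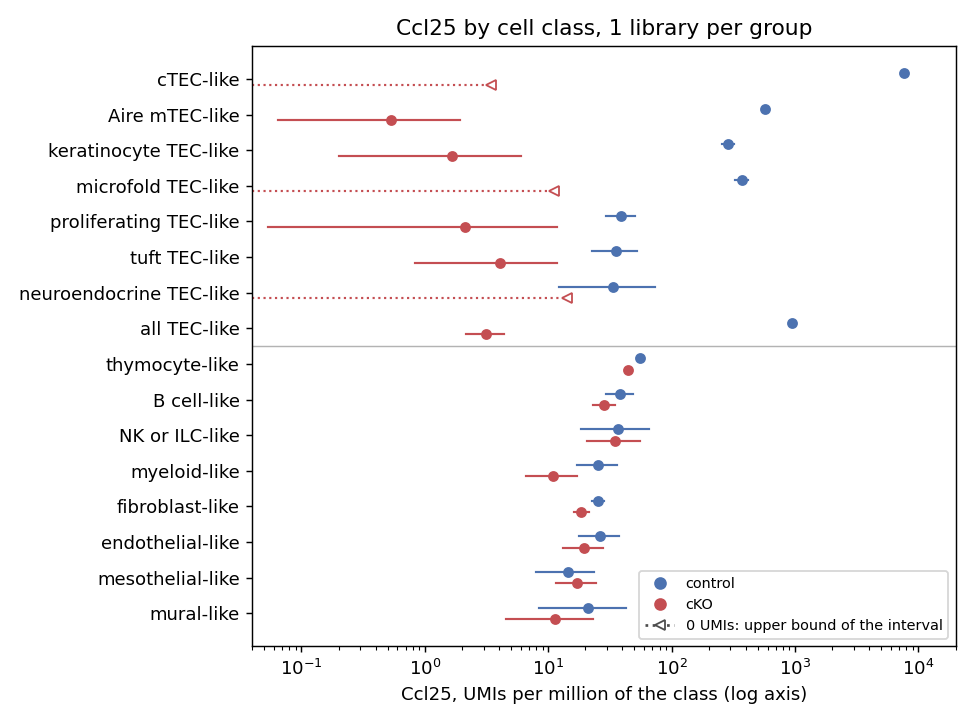
Ccl25 in CPM of each class on a log axis for the control and cKO libraries, with exact Poisson 95% intervals as bars and, where a class had 0 UMIs, an open arrow at the upper bound. Control values run from 14.3 CPM in mesothelial-like to 7658 CPM in cTEC-like cells, and TEC-like cells of the cKO library stand at 3.11 CPM.

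Foxn1, the transcription factor that drives TEC development and whose regulatory sequence drives Cre here, was higher in cKO epithelium together with its nearest neighbours. Foxn1 (ENSMUSG00000002057, chromosome 11, 78357577 to 78386558) went from 75.2 to 136 CPM in TEC-like cells, a log2 ratio of 0.85 [0.74, 0.97]. In cTEC-like cells it went from 143 to 405 CPM, a log2 ratio of 1.50 [1.18, 1.83], and in Aire mTEC-like cells from 109 to 176 CPM, a log2 ratio of 0.69 [0.52, 0.86]. Unc119 (ENSMUSG00000002058, 8.4 kb from Foxn1), which encodes a lipid-binding trafficking protein, went from 19.7 to 99.4 CPM in TEC-like cells, a log2 ratio of 2.33 [2.14, 2.53], and from 75.1 to 460 CPM in cTEC-like cells.

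Unc119 was also higher where Foxn1 was near the limit of detection. Outside the TEC-like class it went from 12.1 to 25.1 CPM, a log2 ratio of 1.06 [0.93, 1.18], while Foxn1 had 0.78 and 0.86 CPM. The overlapping pair Slc13a2os and Slc13a2, 7.9 and 10.5 kb away on opposite strands, had log2 ratios of 1.95 and 1.35 in TEC-like cells. Which of the pair the tags came from is uncertain, since the strand use of the counting is not given in the sources used here. Pigs, 14.8 kb away, had a log2 ratio of 0.42 [0.14, 0.71] in TEC-like cells, and the 21 genes 100 to 600 kb away had a median of -0.02. Unc119 and the pair were singled out after their values were seen.

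**Figure D2:**
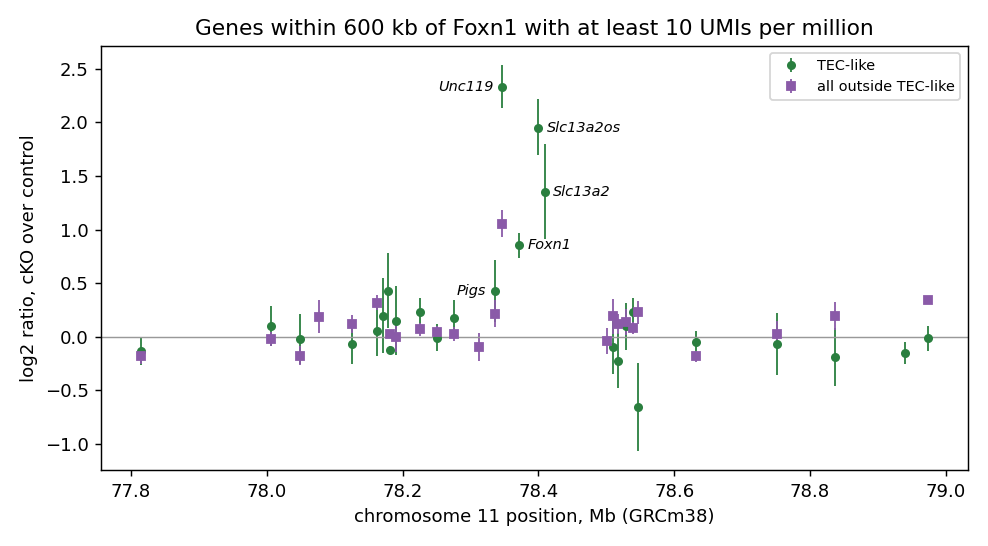
Log2 ratio of cKO over control against position in Mb on chromosome 11 for genes within 600 kb of Foxn1, in TEC-like cells (circles) and in all other cells (squares), with exact 95% intervals as bars. Unc119 stands at 2.33 in TEC-like and 1.06 in other cells, away from the farther genes, whose medians are -0.02 and 0.07.

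The make-up of the CD45-depleted thymus was compared next. TEC-like cells were 12.0% [11.1, 12.9] of the kept control cells and 12.2% [11.3, 13.2] of the cKO cells, a log2 ratio of 0.03 [-0.13, 0.18] whose interval included 0. These are shares of captured cells from 1 library per genotype, so they do not measure the number of TEC per thymus. Endothelial-like cells were 2.98% (152 cells) and 4.47% (201 cells), a log2 ratio of 0.59 [0.29, 0.89], and mesothelial-like cells were 0.960% (49 cells) and 1.98% (89 cells), a log2 ratio of 1.05 [0.55, 1.54]. Among cells without blood classes these ratios were 0.50 [0.21, 0.79] and 0.96 [0.47, 1.45], and fibroblast-like cells were 49.0% of control and 43.9% of cKO cells, a log2 ratio of -0.16 [-0.26, -0.06]. Over kept cells the ratio for fibroblast-like cells was -0.08 [-0.20, 0.05], and 0.06 with each library clustered alone.

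Blood-type cells passed the CD45 depletion in large number, so their shares depend on that step too. CD45-type classes made up 63.3% of control and 61.1% of cKO cells, and thymocyte-like cells 47.1% and 45.6%. B cell-like cells were 2.23% and 4.05%, with different clusters holding most of them, cluster 20 in control (62 cells, against 41 in cKO) and cluster 13 in cKO (141 cells, against 52 in control). NK or ILC-like cells were 0.823% and 1.31% and myeloid-like cells 1.06% and 1.85%, of which cluster 22 held 42 and 52 cells and cluster 25 held 12 and 31 cells. With each library clustered alone, these last log2 ratios, 0.67 and 0.80, turned to -0.37 and -0.58. Unnamed cluster 16, led by neutrophil genes, went the other way with 118 and 30 cells, and unnamed cluster 27 held 22 and 0 cells. Unnamed clusters held 12.0% of control and 8.24% of cKO cells among Ptprc-positive clusters, and 1.86% and 1.76% among the others.

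Within the epithelium, cTEC-like cells were 4.57% (28 of 613) of control and 7.45% (41 of 550) of cKO TEC-like cells, a log2 ratio of 0.71 [0.03, 1.38]. That interval included 0 with the looser filter (0.59 [-0.06, 1.24]), with at most 5% mitochondrial UMIs (0.60 [-0.17, 1.36]) and with each library clustered alone (0.38 [-0.25, 1.01]). Proliferating TEC-like cells, whose leading genes held the muscle genes Acta1 and Myl1 beside cell division genes, were 5.87% (36 cells) and 2.36% (13 cells), a log2 ratio of -1.31 [-2.21, -0.41]. No such class was found with the looser filter or without the highest 5% of doublet scores, and with each library clustered alone it held 59 and 0 cells. The intervals for Aire mTEC-like (-0.17 [-0.43, 0.08]), keratinocyte (0.00 [-0.47, 0.47]), tuft (0.50 [-0.10, 1.10]), microfold (-0.71 [-1.55, 0.13]) and neuroendocrine TEC-like cells (0.04 [-1.08, 1.16]) included 0. These readings changed with each library clustered alone, where the values were -0.80 [-1.07, -0.52] for Aire mTEC-like, 0.78 [0.26, 1.30] for keratinocyte and -0.85 [-1.64, -0.05] for microfold TEC-like cells. The microfold interval also excluded 0 with at most 5% mitochondrial UMIs (-1.04 [-1.89, -0.20]) and at resolution 2 (-0.92 [-1.69, -0.15]). Unnamed subclusters held 33.4% of control and 37.1% of cKO TEC-like cells.

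**Figure D3:**
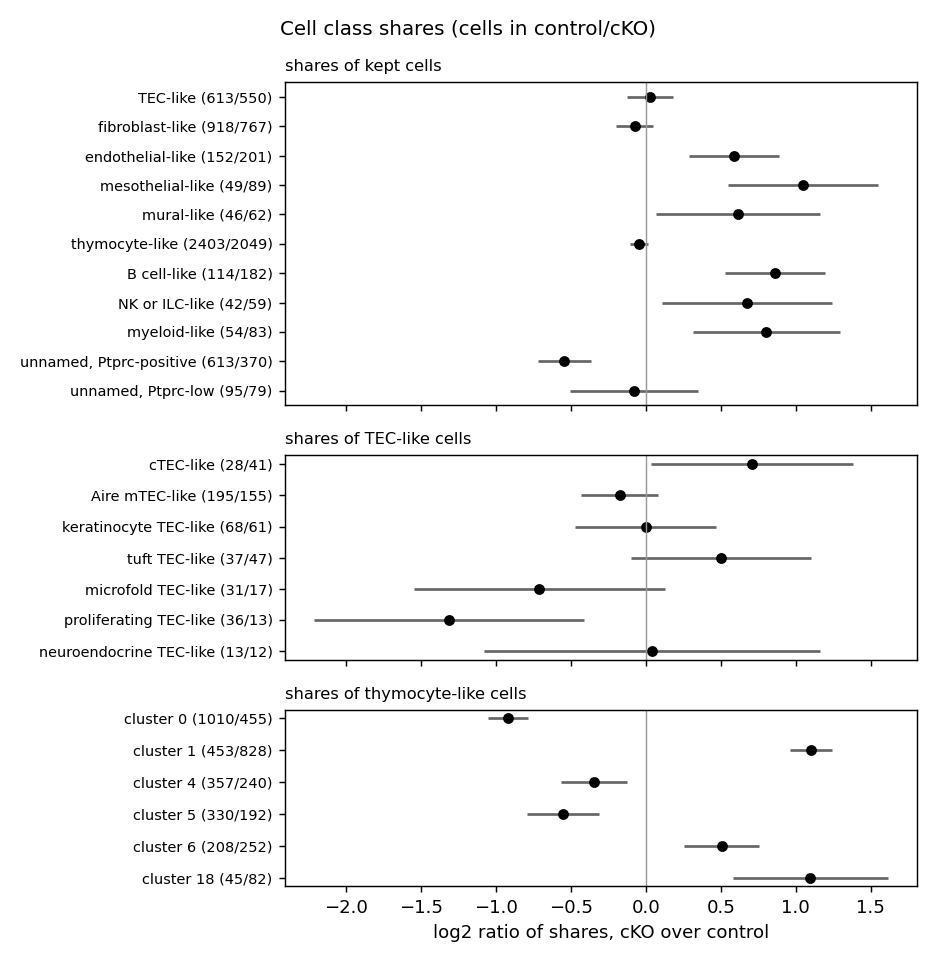
Log2 ratio of the share of cells, cKO over control, for classes of kept cells, TEC-like classes and thymocyte-like clusters, with Katz 95% intervals as bars and the cells in each library beside the names. Thymocyte cluster 0 stands at -0.92 and cluster 1 at 1.10, while all TEC-like cells stand at 0.03.

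In TEC-like cells, besides Ccl25, cKO had lower levels of cell cycle genes and of tissue antigens, and higher levels of stress genes. These values were summed over subclusters and carry changes in their shares, such as the 36 control and 13 cKO cells of the proliferating class. The cell cycle list had a median log2 ratio of -0.54 [-0.61, -0.43] with 0 of 17 members higher (percentile 0.00 of matched random lists). Examples were Top2a, which untangles replicated DNA (-0.89), and Ube2c, which acts in mitotic exit (-0.63). Tissue antigens, which mTEC express for tolerance, had a median of -0.56 [-0.72, -0.42] with 3 of 8 members higher (percentile 0.00), but 0.22 in Aire mTEC-like cells alone. Members that were lower included insulin, Ins2 (-1.88), and transthyretin, Ttr (-1.63). Over the alternatives Ins2 ranged from -2.06 to -1.46 and Ttr from -1.88 to -0.40. Medullary maturation genes had a median of -0.13 [-0.24, -0.10] with 12 of 13 lower (below the middle 95% of random lists), including the osteoprotegerin gene Tnfrsf11b (-0.63) and Fezf2, a regulator of tissue antigens (-0.33). The cell cycle median was -0.07 without the highest 5% of doublet scores but -4.37 after free-RNA subtraction. The subtracted profile held cycling thymocytes, with Top2a at 1152 CPM in cluster 4 and 1164 CPM in cluster 6. Counts under 0 were set to 0, so -4.37 does not measure a larger loss. The tissue antigen median was 0.04 with the looser filter but -1.24 without the highest 5% of doublet scores and -1.14 without subclusters led by another class, and the medullary median 0.04 and Fezf2 0.03 after free-RNA subtraction.

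Extracellular matrix genes had a median of 0.51 [0.41, 0.59] in TEC-like cells with 16 of 20 higher (percentile 100), including Lama2 (1.44) and Dcn (0.69), which encode laminin and decorin. Lama2 ranged from 0.43 to 1.82 over the alternatives. The matrix median was -0.22, and Dcn -0.42, without the TEC subclusters led by genes of another class, among them a subcluster led by fibroblast genes with 1 control and 11 cKO cells. Also left out were the thymocyte-led subcluster 8 and subcluster 5 (38 and 49 cells). Subcluster 5 had mural leading genes but 7 raised markers of Ccl21-type mTEC, so this setting may drop epithelial cells too. Dissociation stress genes, which rise when tissue is digested, were higher for 16 of 16 members (median 0.22 [0.20, 0.26], percentile 100), including Ier3 (0.73) and Socs3 (0.47).

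The 16 other lists stayed within the middle 95% of random lists in TEC-like cells. Chemokines had a median of 0.02, with Ccl22 at -1.92 and Ccl9 at -1.27. Thymocyte support had 0.05, cTEC antigen processing 0.17, immunoproteasome and class I -0.04, class II 0.05 and TEC transcription factors 0.06. Interferon response had 0.07, hypoxia and glycolysis -0.08, fibroblast growth and morphogen signals -0.03, and endothelial thymic portal and adhesion 0.16. Lists of blood cell genes had medians of 0.04 for thymocyte receptors, -0.04 for DN stage, 0.04 for DP stage, 0.06 for SP stage, -0.02 for gamma-delta and -0.10 for CD45-positive carry-over.

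By size, the genes higher in cKO TEC-like cells were Klk1 (1.70), a tissue kallikrein, Kirrel3 (1.38), the peptide hormone gene Pyy (1.18), Stxbp5l (1.15), Mucl2 (1.09), the neutrophil gene Camp (1.01), Foxn1 (0.85) and the basal keratin gene Krt5 (0.76). Besides Ccl25, those lower were the lactoferrin gene Ltf (-2.24), Gm10076 (-1.16), Wfdc2 (-1.12), the neurotensin gene Nts (-0.94), the metallothionein gene Mt2 (-0.67) and Ptgds (-0.60). A single cell held 43.8% of the cKO UMIs of Klk1, and without each library's top cell Klk1 and Camp had ratios of 1.10 and 0.55. With equal weight per cell Camp had 0.09. Wfdc2 went to -0.14 without the highest 5% of doublet scores. The lowest values over the alternatives were 0.50 for Pyy, 0.38 for Stxbp5l and 0.52 for Mucl2. Gm10076 has near-identical copies in the genome, so its value is uncertain.

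In cTEC-like cells, the class that had the most Ccl25, chemokine and class II genes were higher and interferon response genes lower in cKO, from 28 control and 41 cKO cells. Of 19 lists, 6 lay above and 1 below the middle 95% of random lists, so the chemokine and class II lists did not stand alone. Chemokines had a median of 0.34 [0.18, 0.70] (8 of 12 higher, with Ccl25 among the 12, percentile 98.4), including Ccl5 (2.56) and Cxcl10 (2.01), attractants of T cells. The chemokine median was 0.09 without the filter on low genes and 0.17 without the highest 5% of doublet scores, and Ccl5 and Cxcl10 went to 0.32 and 0.87 with each library clustered alone. Class II genes, which act in antigen presentation to CD4 thymocytes, were higher for 9 of 9 members (median 0.25 [0.12, 0.32], percentile 99.3), including H2-Oa (0.58) and H2-DMa (0.35). Interferon response genes had a median of -0.30 [-0.49, -0.05] with 11 of 15 lower (below the middle 95% of random lists), including Gbp2 (-1.21) and Isg15 (-0.57). Antigen processing genes of cTEC (-0.13), thymocyte support (0.04) and TEC transcription factors (0.00) stayed within the middle 95%. The interferon median turned to 0.35 with each library clustered alone and to 0.10 without the highest 5% of doublet scores, where the class II median was -0.01. Gbp2 ranged from -1.81 to -0.07 over the alternatives.

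By size, cTEC-like cells of cKO had more Unc119 (2.60) and Cxcl10, of which 1 cell held 61.8% of the cKO UMIs. They also had more of the neutrophil genes Retnlg (5.52), Ngp (4.35), S100a9 (4.27), Lcn2 (4.16), S100a8 (4.10) and Camp (2.46). For each of those 6, 1 cell held at least 95.3% of the cKO UMIs, and without each library's top cell the ratios were 0.00, -2.08, -1.61, -2.48, -2.75 and -1.59. Besides Ccl25, the lower genes were the basal keratin gene Krt14 (-2.87, and -1.99 without each library's top cell, which held 64.1% of the control UMIs), the splicing regulator Rbfox1 (-1.90), Inmt (-1.75), 2810407A14Rik (-1.72), Gm10076 (-1.34) and A630023P12Rik (-1.17).

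Aire mTEC-like cells had higher dissociation stress genes in cKO (15 of 16, median 0.27 [0.22, 0.34], percentile 99.99), including Jun (0.62) and Ier3 (0.47), and the median moved to 0.03 with each library clustered alone. Of 21 lists, 6 lay above and 2 below the middle 95% of random lists. Tissue antigens (0.22) and medullary maturation (-0.03) stayed within the middle 95%. Genes chosen by size were Pomc (2.99), Sbp (2.69), Nav3 (2.63) and Klk1 (1.78), which were higher, and, besides Ccl25, the lens crystallin gene Cryaa (-3.75), Cntn5 (-2.38) and Dppa3 (-2.35), which were lower. In cKO, 1 cell held 96.4% of the UMIs of Sbp, 67.0% of those of Klk1 and 56.8% of those of Nav3, and without each library's top cell the ratios were 0.15, 0.54 and 1.81. Klk1 turned to -1.06 with each library clustered alone, and with doublets kept Sbp and Cntn5 turned to -2.67 and 0.88 and Nav3 moved to 0.30. Pomc ranged from 1.50 to 3.35 over the alternatives.

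Fibroblast-like cells, 918 in control and 767 in cKO, had higher interferon-linked genes and chemokines in cKO, within a broad shift in which 11 of 19 lists, several of blood cell genes among them, lay above and 2 below the middle 95% of random lists. These sums also carry shifts between clusters, with cluster 2 at 47.6% and 55.9% of the class and cluster 7 at 29.6% and 24.0%. The interferon response list had a median of 0.35 [0.28, 0.46] with 14 of 16 members higher (percentile 100), including Isg15 (0.98) and the GTPase gene Iigp1 (0.77). Immunoproteasome and class I genes, which prepare peptides for presentation, were higher for 14 of 14 members (median 0.34 [0.27, 0.38], percentile 100), including Tap2 (0.69) and Psmb8 (0.54). Chemokines had a median of 0.42 [0.30, 0.46] with 12 of 15 higher (percentile 100), including Cxcl9 (2.78), an interferon-induced attractant of T cells, and Ccl7 (0.99), an attractant of monocytes. Dissociation stress genes were higher as well (15 of 16, median 0.21, percentile 100), including the heat shock genes Hspa1a (0.48) and Hspb1 (0.39). Fibroblast growth and morphogen signals stayed within the middle 95% (0.04).

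Other fibroblast-like genes chosen by size were the cytokine gene Il6 (0.87) and the hyaluronan synthase gene Has1 (0.75), which were higher, and Zbtb16 (-1.25), Gm10076 (-1.13), the Wnt inhibitor gene Dkk2 (-0.98) and Tsc22d3 (-0.97), which were lower. Zbtb16 and Tsc22d3 are known targets of glucocorticoids. A single cell held 66.8% of the cKO UMIs of Cxcl9, which had a ratio of 1.55 without each library's top cell. Blood-cell transcripts moved too, with a carry-over median of 0.16 (Cd52 1.10, Trbc1 0.42) that turned to -0.61 with the looser filter.

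Endothelial-like cells carried more cell cycle and blood-cell transcripts in cKO, and these values turned with the filter on cells. Of 17 lists, 5 lay above and 3 below the middle 95% of random lists. The cell cycle list had a median of 1.57 [1.21, 1.89] with 16 of 17 higher (percentile 100), including Top2a (3.29) and Mki67 (2.79). The CD45-positive carry-over list had a median of 1.12 [0.88, 1.66] with 10 of 11 higher (percentile 100), including Ptprc (2.65), which encodes CD45, and Coro1a (2.04). With the stricter filter these medians were -0.59 and -0.76. Extracellular matrix genes were lower (14 of 17, median -0.44 [-0.68, -0.37], percentile 0.00), including Dcn (-1.14) and Sparc (-0.54), a median that shrank to -0.24 with the stricter filter and -0.17 without the highest 5% of doublet scores, and thymic portal and adhesion genes stayed within the middle 95% (-0.24). By size, the T cell receptor gene Tcrg-C1 (3.91), Runx1 (3.20), Tnfsf11 (3.05) and Plac8 (2.98) were higher, which with the stricter filter were 0.57, -0.52, -0.81 and 0.09. Igfbp3 (-2.09), Thbs1 (-2.06), Thrsp (-1.39) and Tsc22d3 (-1.22) were lower.

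Cells that received the thymocyte-like name moved from double-positive towards double-negative and gamma-delta genes in cKO. Unnamed clusters with Il2ra and Kit lie outside this class and went both ways. As shares of CD45-type cells, cluster 12 (Il2ra 241 CPM, Kit 123 CPM) and cluster 14 (193 and 83.8 CPM) had log2 ratios of -0.88 and -0.64. Cluster 11 (328 and 71.5 CPM) had 0.51. Cluster 0, with Rag1 at 861 CPM, Cd4 at 544 CPM and Ccr9 at 1001 CPM over both libraries, was 42.0% of control and 22.2% of cKO thymocyte-like cells, a log2 ratio of -0.92 [-1.06, -0.79]. Cluster 1, with Il2ra at 417 CPM and Tcrg-C1 at 629.7 CPM but Cd4 at 2.96 CPM, was 18.9% and 40.4%, a log2 ratio of 1.10 [0.96, 1.24]. The other thymocyte clusters had log2 ratios of -0.34 (cluster 4), -0.55 (cluster 5), 0.51 (cluster 6) and 1.10 (cluster 18). The name of cluster 18 is weak, with a marker level of 0.21 and 0 thymocyte markers among its leading genes. Those genes included Icos, Cxcr6, Il23r and Il22, and Rag1 stood at 3.38 CPM. All thymocyte-like cells had passed a step that removes CD45-positive cells, so their shares are not those of the intact thymus. With each library clustered alone, the share of clusters high in Rag1 had a log2 ratio of -0.59.

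Over all thymocyte-like cells, 8 of 15 lists lay above and 3 below the middle 95% of random lists, so a list outside it was common in this class. DP stage genes had a median of -0.82 [-0.90, -0.75] with 8 of 10 lower (percentile 0.00), including Cd4 (-1.28), the CD4 co-receptor, and Rag1 (-1.08), which recombines antigen receptor genes. DN stage genes had a median of 0.32 [0.23, 0.41] with 7 of 8 higher (percentile 99.97), including the interleukin 2 receptor gene Il2ra (0.57) and the Notch target Hes1 (0.56). Gamma-delta genes were higher for 5 of 5 members (median 0.53 [0.40, 0.59], percentile 100), including Tcrg-C2 (0.71) and Tcrg-C1 (0.57). SP stage genes had a median of 0.12 (5 of 9 higher, percentile 97.9), with Klf2, a regulator of exit from the thymus, at 0.80 and Itm2a at -0.52, and turned to -0.05 with each library clustered alone. Ccr9, the receptor for Ccl25, went from 252 to 113 CPM, a log2 ratio of -1.15, and stood at 57.6 CPM in cluster 1 against 1001 CPM in cluster 0.

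The thymocyte receptor list as a whole had a median of 0.18 [0.12, 0.23] with 7 of 10 higher (percentile 99.8), including the interleukin 7 receptor gene Il7r (0.45), and turned to -0.02 with each library clustered alone. Interferon response genes were higher in cKO thymocyte-like cells (11 of 14, median 0.36 [0.29, 0.45], percentile 100), including Isg15 (0.75) and Bst2 (0.45), as were dissociation stress genes (15 of 16, median 0.29 [0.27, 0.32], percentile 100), including Jun (0.78) and Socs3 (0.70). The list values of this class also carry its shift from cluster 0 to cluster 1, since they were summed over clusters. Genes chosen by size were Gm4632 (0.76), Ifi27 (0.73) and Tmem108 (0.73), which were higher with Isg15, and Gm32004 (-1.48), the histone gene Hist1h2ap (-1.27) and Glcci1 (-1.19), which were lower with Cd4. Gm4632 and Hist1h2ap have near-identical copies, so their values are uncertain.

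**Figure D4:**
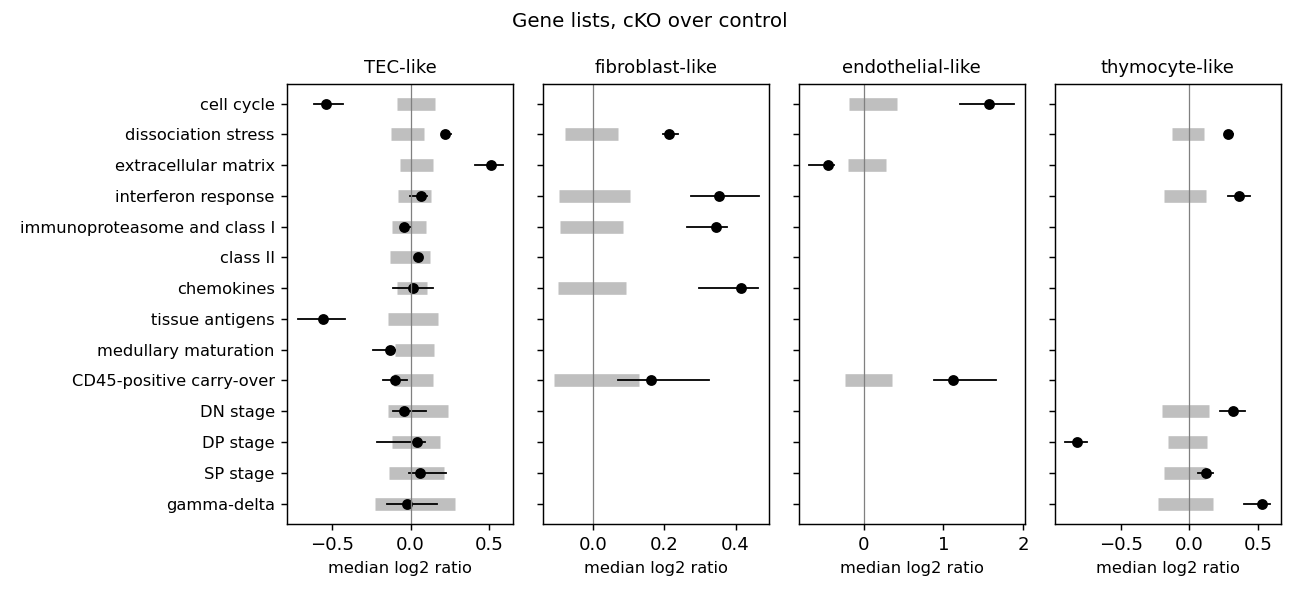
Median log2 ratio of cKO over control for fixed gene lists in 4 classes, with counting intervals as thin bars and the middle 95% of matched random lists as grey bands. Interferon response stands at 0.35 in fibroblast-like and 0.36 in thymocyte-like cells, against 0.07 in TEC-like cells, and DP stage stands at -0.82 in thymocyte-like cells, whose values also carry the shift between clusters.

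These are measured differences between 2 libraries, and no explanation is drawn from them here.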

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

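No paired analysis was possible because each genotype had 1 library and no label pairs them. A value counts as kept when the alternative stayed within the counting interval of the chosen analysis, as turned when the sign of a called value changed, and otherwise as moved. For Ccl25, 14 of 22 settings over 3 results kept the value, 8 moved it and 0 turned it, with a range of -11.39 to -6.87 in TEC-like cells. The value of -11.39 came from free-RNA subtraction, whose thymocyte-like profile itself held Ccl25 UMIs, so it does not measure a larger loss. Where a class had 0 UMIs in cKO, as cTEC-like cells did in the chosen analysis, the value is a bound from a floor of 3 counts and moves with the depth of the class. For the 24 list medians outside the middle 95% of random lists that were tried, 191 of 286 settings kept the value, 74 moved it and 21 turned it. For 23 medians within it, 222 of 292 kept the value and 70 moved it. Other lists of these classes had no alternatives run. For genes named in the report, 931 of 1287 kept the value, 309 moved it and 47 turned it, without the filter on lists and the median-ratio scaling, which leave a gene's ratio as it is or shift all genes alike. For the main shares, 60 of 64 kept the value, 4 moved it and 0 turned it, and for the other shares 46 of 49 kept it, 1 moved it and 2 turned it. A share could count as turned only where its interval in the chosen analysis excluded 0. The fibroblast-like share therefore counts as moved although it changed sign from -0.08 to 0.06, and the TEC-like share as kept although it reached -0.06.

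Foxn1 in TEC-like cells ranged from 0.78 to 1.21 and Unc119 from 1.88 to 2.63. The TEC-like share ranged from -0.06 to 0.12, the endothelial-like share from 0.50 to 0.61 and the mesothelial-like share from 0.96 to 1.15. The share of clusters high in Rag1 ranged from -1.04 to -0.59. Median-ratio scaling over genes with at least 50 CPM turned 0 values. Shares after free-RNA subtraction were not run, since the subtraction acts on sums per class. The looser filter gave no microfold or proliferating TEC-like class, and the removal of the highest 5% of doublet scores gave no proliferating class. With each library clustered alone the cKO library had no proliferating TEC-like class, so that share has no value there. Gene lists are named in short below, as stress for dissociation stress, matrix for extracellular matrix, and carry-over for CD45-positive carry-over. Genes and secondary values are given below where they turned, and the main values also where they moved; the cause was not tested. The interval of the cTEC-like share of TEC-like cells, 0.71 in the chosen analysis, included 0 with the looser filter, with at most 5% mitochondrial UMIs and with each library clustered alone.

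With a looser filter (200 genes and 500 UMIs), log2 ratios that moved or turned were 0.0394 for tissue antigens, -0.70 for cell cycle and 0.36 for matrix in TEC-like cells. Endothelial-like cells gave 1.04 for cell cycle and 0.29 for carry-over. Fibroblast-like cells gave 0.48 for chemokines, 0.25 for stress, -0.61 for carry-over and -1.07 for Trbc1. Aire mTEC-like cells gave 0.19 for stress. With a stricter filter (1000 genes and 2000 UMIs), log2 ratios that moved or turned were -0.62 for cell cycle in TEC-like cells. Endothelial-like cells gave -0.59 for cell cycle, -0.76 for carry-over, -0.24 for matrix, -0.52 for Runx1, -0.81 for Tnfsf11, -0.83 for Top2a, -1.57 for Mki67 and -0.0607 for Coro1a. Fibroblast-like cells gave 0.48 for chemokines, 0.26 for stress, -0.60 for carry-over, -0.98 for Cd52 and -1.03 for Trbc1. Aire mTEC-like cells gave -3.11 for Sbp. With a mitochondrial share of at most 5%, log2 ratios that moved or turned were -0.63 for cell cycle and 0.36 for matrix in TEC-like cells. Endothelial-like cells gave -0.46 for cell cycle, -0.66 for carry-over, -0.25 for matrix, -0.48 for Runx1, -0.82 for Tnfsf11, -0.46 for Top2a, -1.80 for Mki67 and -0.17 for Coro1a. Fibroblast-like cells gave 0.47 for chemokines, 0.27 for stress, -0.55 for carry-over, -0.99 for Cd52 and -0.98 for Trbc1. In cTEC-like cells there were 0.36 for class II. With called doublets kept, log2 ratios that moved or turned were -2.67 for Sbp and 0.88 for Cntn5 in Aire mTEC-like cells.

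At clustering resolution 2, log2 ratios that moved or turned were -0.91 for DP, 0.32 for gamma-delta, 0.0990 for receptors and 0.26 for stress in thymocyte-like cells. With each library clustered alone, log2 ratios that moved or turned were -11.01 for Ccl25 in cTEC-like cells, -0.59 for the share of clusters high in Rag1, 0.0650 for the fibroblast-like share, -0.17 for the thymocyte-like share, -0.37 for the NK or ILC-like share, -0.58 for the myeloid-like share and -0.80 for the Aire mTEC-like share. Endothelial-like cells gave -0.27 for matrix. Fibroblast-like cells gave 0.19 for stress and 0.48 for carry-over. Thymocyte-like cells gave -0.66 for DP, -0.0494 for SP, 0.26 for gamma-delta, -0.0218 for receptors and 0.21 for stress. Aire mTEC-like cells gave 0.0270 for stress and -1.06 for Klk1. In cTEC-like cells there were 0.77 for chemokines, 0.78 for class II, 0.35 for interferon and 0.45 for Isg15. After subtraction of the free-RNA profile, log2 ratios that moved or turned were -11.39 for Ccl25 in TEC-like cells. TEC-like cells gave 0.0354 for medullary, -0.21 for tissue antigens, 0.52 for stress, -4.37 for cell cycle, 0.84 for matrix and 0.0348 for Fezf2. Endothelial-like cells gave 1.81 for carry-over and -0.34 for matrix. Fibroblast-like cells gave -0.0700 for carry-over and -0.92 for Trbc1. In cTEC-like cells there were 0.44 for class II. With cells thinned to 2000 UMIs, log2 ratios that moved or turned were -6.87 for Ccl25 in TEC-like cells, -6.81 for Ccl25 in cTEC-like cells and 3.56 for control Ccl25 in TEC-like over other cells (4.46 in the chosen analysis).

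With a pseudocount of 10 CPM, log2 ratios that moved or turned were -0.39 for tissue antigens, -0.39 for cell cycle and 0.39 for matrix in TEC-like cells. Endothelial-like cells gave 1.02 for cell cycle. Thymocyte-like cells gave -0.69 for DP, 0.22 for DN, 0.38 for gamma-delta and 0.26 for interferon. With equal weight per cell, log2 ratios that moved or turned were -0.0721 for medullary, 0.14 for stress and 0.20 for matrix in TEC-like cells. Endothelial-like cells gave 0.15 for cell cycle, 0.50 for carry-over and -0.22 for matrix. Fibroblast-like cells gave -0.0713 for carry-over and -0.0658 for Trbc1. Thymocyte-like cells gave -0.71 for DP, 0.64 for DN, 0.28 for SP, 0.98 for gamma-delta, 0.33 for receptors, 0.49 for interferon and 0.47 for stress. In cTEC-like cells there were 0.40 for class II. Without the filter on low genes in the lists, log2 ratios that moved or turned were -0.25 for tissue antigens in TEC-like cells. Fibroblast-like cells gave 0.24 for chemokines. Thymocyte-like cells gave -0.0588 for SP. In cTEC-like cells there were 0.0889 for chemokines. Without the cells in the highest 5% of doublet scores, log2 ratios that moved or turned were -8.89 for Ccl25 in TEC-like cells and -10.61 for Ccl25 in cTEC-like cells. TEC-like cells gave -1.24 for tissue antigens, 0.15 for stress, -0.0746 for cell cycle and 0.0947 for matrix. Endothelial-like cells gave -0.59 for cell cycle, -0.60 for carry-over, -0.17 for matrix, -0.48 for Runx1, -0.86 for Tnfsf11, -0.64 for Top2a, -1.65 for Mki67, -0.0190 for Ptprc and -0.17 for Coro1a. Fibroblast-like cells gave 0.47 for chemokines, -0.25 for carry-over, -0.58 for Cd52 and -0.25 for Trbc1. Thymocyte-like cells gave 0.31 for gamma-delta and 0.26 for stress. Aire mTEC-like cells gave 0.35 for stress, -3.63 for Sbp and -0.0667 for Ier3. In cTEC-like cells there were 0.17 for chemokines, -0.00734 for class II, 0.10 for interferon, -1.82 for Retnlg, -1.80 for Ngp, -2.03 for S100a9, -0.63 for Lcn2, -2.51 for S100a8, -1.72 for Camp and 0.11 for Isg15. Without TEC subclusters led by genes of another class, log2 ratios that moved or turned were -9.44 for Ccl25 in TEC-like cells. TEC-like cells gave -1.14 for tissue antigens, 0.18 for stress, -0.22 for matrix and -0.42 for Dcn. Without each library's cell with the most UMIs of the gene, log2 ratios that moved or turned were 0.00 for Retnlg, -2.08 for Ngp, -1.61 for S100a9, -2.48 for Lcn2, -2.75 for S100a8 and -1.59 for Camp in cTEC-like cells. The removal of the highest 5% of doublet scores, the omission of TEC subclusters led by another class and the omission of top cells were chosen after the data were seen.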

Other observations

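B cell-like cells were 114 in control and 182 in cKO, drawn mostly from different clusters, so their gene differences also carry that shift. Genes higher in cKO were the chemokine receptor gene Ccr6 (1.67), Unc119 (1.65), Basp1 (1.41) and Mir155hg (1.39), the host gene of a microRNA of activated B cells. Lower were Pcdh9 (-3.36), the surrogate light chain genes Vpreb1 (-2.69) and Igll1 (-2.36), which mark early B cell development, and Erg (-2.21). Cluster 13, higher in cKO, held 52 control and 141 cKO cells, and cluster 20 held 62 and 41.

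The tests of Ccl25 outside the epithelium were chosen after the result was seen. Ccl25 in cKO was 11.2-fold [7.97, 16.2] higher outside than inside TEC-like cells, which argues against free RNA as the whole source, since free RNA would reach both. Ccl25 per Elavl1 UMI was 0.176-fold [0.121, 0.246] in TEC-like cells relative to the others, which argues against tags of Elavl1 counted as Ccl25. The level in thymocyte-like over fibroblast-like cells was 2.40-fold [2.07, 2.79], a difference between classes that low transcription in cells keeping the floxed gene could give. A change of the animals other than the deletion remains open as untested.

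The tests of the Foxn1 locus were chosen after the result was seen. With subclusters weighted as in control, Foxn1 still had a log2 ratio of 0.79 [0.66, 0.91], which argues against subcluster make-up as the cause. Unc119 had 1.06 [0.93, 1.18] outside TEC-like cells, as extra copies of the locus carried by the transgene could give, although the construct is not given in the sources used here. A response to Ccl25 loss was probed by the cTEC antigen processing list in cTEC-like cells, -0.13 [-0.19, 0.02] over 7 members, and cannot be told apart from the transgene, since both are in the same library. A biological difference between the 2 libraries remains open as untested.

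For the loss of thymocyte cluster 0, the depletion test was chosen after the result was seen and the test of low-UMI cells before it. Ptprc RNA and the log2 ratio of shares had a rank correlation of 0.254 [-0.297, 0.678] over 15 blood clusters, which leaves more complete CD45 depletion open, since the interval spans 0 and RNA is not surface protein. The clusters with the most Ptprc went both ways, with 5 (1502 CPM) and 0 (1378 CPM) at -0.55 and -0.91 and 21 (1253 CPM) at 0.73. Among cells at or above the control median depth of the cluster, the log2 ratio was -0.98 [-1.17, -0.78], which argues against a loss of low-UMI cells. The ratio was -0.59 with each library clustered alone, so its size may depend on the joint clustering, and a biological difference in thymocyte development remains open as untested.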
